A study of Homo sapiens with 85 samples.

How the data were processed

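Gene expression was measured in biopsies of 2 tissues, the transformation zone of the cervix and the endometrium, from volunteers in 3 groups. Controls used no hormonal contraceptive and were sampled in the mid-secretory phase. The other groups used depot medroxyprogesterone acetate (DMPA), an injected progestin given at 150 mg, or an intrauterine system that releases levonorgestrel (LNG-IUS), each for at least 6 months. Per the labels' protocols, frozen tissue was extracted with TRIzol, RNA was amplified to cDNA with the NuGEN Ovation Pico WTA V2 kit, and biotin-labelled cDNA was read on the Affymetrix array type Human Gene 1.0 ST, 1 array per sample. The 85 arrays comprised 20 control, 15 DMPA and 17 LNG-IUS cervical samples and 12 control, 8 DMPA and 13 LNG-IUS endometrial samples. The labels gave 12 endometrial controls where the series text gave 11, and all 12 were kept.

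The authors deposited 1 table of 28869 rows (probe sets) with a value for each of the 85 arrays, used here as log2 values, a scale inferred from the range of the values, -7.46 to 7.00, and not stated in the labels. Background correction, summarization and normalization were not given in the sources used here. Every row of the deposited log2 table had a median of 0 over the arrays, so the table held deviations from each row's median and no expression level. Array medians lay between -0.02 and 0.04, and the SD of an array's values lay between 0.243 and 0.454 in the cervix and between 0.401 and 0.576 in the endometrium. No detection signal was used, and the number of arrays limits the precision. The highest correlation between 2 arrays was 0.848, so no sample was counted as a repeat of another. If the values were in another log base, every log2 change and fold below would scale with it, while the tests would not change.

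Probe sets were named from the platform annotation. Of the rows, 19310 had 1 gene symbol, 1752 had several and 7807 were not listed there. Of the rows with 1 symbol, 19279 matched the reference gene table. The rows of a gene were averaged (684 genes had more than 1 row), which left 18354 genes. No genome was used, so no coordinates are given.

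All user samples and some controls had titles of a form called here PR, and the other controls had titles of a form called here bx. The cervical controls comprised 7 PR and 13 bx samples and the endometrial controls 3 PR and 9 bx samples. The bx titles also differed among themselves, in the number after bx and in capital letters, and this was not modelled. The meaning of the PR and bx forms was not stated. Because a difference between them would be read as an effect of the contraceptive, title series was a term in each model. Comparisons with control therefore rested on the 7 and 3 PR controls, and the bx controls added to the estimate of the spread. Each tissue was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 for block correlations. P-values were 2-sided and adjusted by Benjamini-Hochberg over the 18354 genes, and a gene was called at an adjusted p under 0.05. Changes between tissues were tested in 1 model of all 85 arrays with a title-series term in each tissue. The p-values measure the spread between these samples.

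The 37 gene lists (hormone response, host defence, cell type markers and sample quality) were fixed beforehand. They were tested with limma's camera, at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated from the data, and adjusted over the lists of a comparison. Members called were counted after adjustment over all genes and over the list alone. Genes named in the text were, per comparison, the 6 largest rises and the 6 largest falls among called genes, up to 2 called members of each list, and a fixed set of hormone, epithelial and immune genes, of which 13 were measured and FKBP5 was not. Where no gene was called, the 3 rises and 3 falls of lowest p were named. The endometrial and interaction accounts use part of the genes that this rule gave. XIST, genes of the Y chromosome, unnamed gene models, immunoglobulin and T cell receptor segments and small RNAs were left out.

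Both tissues came from 29 participants, identified by a shared code in the titles, so the pairing is by design. Over genes, the deviations of the 2 samples of a participant had a median correlation of 0.02 (range -0.19 to 0.25), against -0.000822 for samples of different participants. The consensus correlation with the participant as a block was 0.0165.

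The models, samples, covariates, gene lists and most alternatives were fixed before the data were examined. The design planned a trend of the prior variance over the mean level and the brightest row per gene; a table without levels allowed neither, so the trend was dropped and rows were averaged. Alternatives changed 1 choice at a time, except that sharing the title-series term between tissues also put both tissues in 1 fit: the title-series term left out, as a random block or shared by the tissues; only PR samples; every row with a symbol; renewed quantile normalization; median centring; robust eBayes; array weights; a covariate for tissue composition; and each endometrial PR control left out. Alternatives added after seeing the data were leaving out the genes of lowest SD, eBayes with a trend over the mean of the centred values, each tissue's own spread for comparisons between tissues, both tissues in 1 fit with a title-series term in each for comparisons within a tissue, and leaving out PR controls there. Tests of single scores were exact permutation tests over all splits.

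The models were tested once per comparison on simulated data with known changes in part of the 18354 genes. Noise was normal, independent between genes and equal in spread over the groups. The shares below therefore leave out correlation between genes and unequal spread. Of genes given a log2 change of 1, the share recovered was 97.0% for cervical DMPA, 95.5% for cervical LNG-IUS and 98.5% for cervical LNG-IUS against DMPA. In the endometrium it was 79.1% for DMPA, 95.5% for LNG-IUS and 91.0% for LNG-IUS against DMPA. For a log2 change of 0.5 the endometrial shares were 46.3%, 56.7% and 77.6%. In the same order, 16 of 196, 13 of 194 and 12 of 209 calls in the cervix and 10 of 157, 6 of 173 and 9 of 188 in the endometrium were of genes given no change, above the nominal 5% in the cervix and for endometrial DMPA.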

Results

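Expression of 18354 genes was compared in 85 biopsies of the cervical transformation zone and the endometrium. The transformation zone is where squamous and columnar epithelium of the cervix meet, and the endometrium is the lining of the uterus. Samples came from users of no hormonal contraceptive (20 cervical and 12 endometrial controls), of injected DMPA (15 and 8) and of the LNG-IUS (17 and 13). The title of the series names host defence genes as its subject. Values were deviations of log2 expression from the median of each gene, so changes between groups are given and absolute levels are not. Changes against control were measured from the controls with PR titles, 7 cervical and 3 endometrial, with errors as standard errors from limma.

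The control tissues differed in genes of their known cell types. In PR controls, the squamous epithelial genes SERPINB3 (log2 change -6.93 ± 0.50), SPRR3 (-6.65 ± 0.72) and KRT13 (-6.45 ± 0.65) were lower in the endometrium than in the cervix. S100A8, a neutrophil and squamous epithelial protein, was also lower (-6.39 ± 0.64), as was JCHAIN, the joining chain of polymeric immunoglobulin (-5.46 ± 0.94). PAEP, the glycodelin gene of secretory glands, was higher (5.37 ± 0.72), as were GNLY, a granule protein of killer lymphocytes (4.46 ± 0.53), HAND2, a transcription factor of endometrial stroma (3.29 ± 0.33), and NCAM1, a natural killer cell marker (1.44 ± 0.33). HBB, the beta chain of hemoglobin, was lower in the endometrium (-3.69 ± 0.86). By limma with Benjamini-Hochberg adjustment 3870 genes were called, 2328 higher and 1542 lower in the endometrium, and the adjusted p of the 10 named genes was at most 0.000764. Without endometrial control replicates 2 and 3, 2419 and 2524 genes were called, and HBB was at -2.97 without replicate 3 and GNLY at 5.05 without replicate 1. SPRR3 lost its call with a trend in eBayes (adjusted p = 0.193, range over its alternatives 1.65e-13 to 0.193).

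The cervix of DMPA users was compared with control cervix to ask which genes the injected progestin changes there. IQGAP1, a scaffold protein of the cytoskeleton, had a log2 change of -0.21 ± 0.05 and lay below the control mean in 15 of 15 samples, and TMCO6 had 0.23 ± 0.05. PCSK5, a proprotein convertase, was at -0.57 ± 0.14, FRY at -0.39 ± 0.10, the ribosomal protein gene RPL8 at 0.22 ± 0.06 and ZNF774 at 0.29 ± 0.08. The progesterone receptor gene PGR was at -0.71 ± 0.29 and PAEP at -0.88 ± 0.33, while the estrogen receptor gene ESR1 was at 0.18 ± 0.10 and the neutrophil chemokine CXCL8 at -0.46 ± 0.48. None of these genes passed the test with the title-series term. By limma with Benjamini-Hochberg adjustment 0 of 18354 genes were called, and 801 had an unadjusted p under 0.05. The lowest adjusted p, that of IQGAP1, was 0.406. Without the title-series term, which puts all 20 controls against the users, 222 genes were called, 138 higher and 84 lower, and PGR (-1.03 ± 0.22), PCSK5 (-0.48) and RPL8 (0.23) were among them.

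By camera 8 of the 37 lists shifted in the cervix with DMPA, with small changes per gene. None of the 8 calls held with an estimated correlation: the adjusted p was 0.285 with an estimated correlation for ribosomal proteins and 0.855 with an estimated correlation for each of the other 7. Ribosomal protein genes rose (16 of 16 measured members above 0, median log2 change 0.08, adjusted p = 6.03e-09). Genes of interstitial collagens and matrix fell (16 of 17 below 0, median -0.46, adjusted p = 5.89e-07). The cell cycle list (median -0.19), the secretory-phase list (-0.13) and the markers of fibroblasts and stroma (-0.34), natural killer cells (-0.11) and T cells (-0.12) also fell, as did inflammatory chemokines and cytokines (-0.16). No member was called over all genes, and adjusted over the list alone 3 ribosomal protein genes and no member of the collagen list were called. Without the title-series term the cell cycle median was 0.19, and with it as a random block 0.03.

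The cervix of LNG-IUS users was compared with control cervix in the same way. TRMT1, a tRNA methyltransferase, was at a log2 change of -0.20 ± 0.05, ZNF594 at -0.41 ± 0.12 and DEPDC4 at -0.16 ± 0.05. SMIM19 was at 0.35 ± 0.10, RBM3, a cold-inducible RNA-binding protein, at 0.33 ± 0.10, and RPP14, a subunit of ribonuclease P, at 0.24 ± 0.07. PAEP was at -0.62 ± 0.33, PGR at 0.01 ± 0.29, ESR1 at 0.17 ± 0.10 and CXCL8 at -0.29 ± 0.47. None of these genes passed the test with the title-series term (limma, adjusted p = 1.00 for each). By limma 0 genes were called and 407 had an unadjusted p under 0.05. Without the title-series term 538 genes were called, 354 higher and 184 lower, SMIM19 (0.35), RBM3 (0.41) and RPP14 (0.23) among them, and PGR was at -0.31.

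By camera 4 lists shifted in the cervix with the LNG-IUS, and all 4 calls were lost with an estimated correlation (adjusted p = 0.935 with an estimated correlation for each). Type I interferon-stimulated genes fell (18 of 19 below 0, median -0.26, adjusted p = 1.78e-06), as did collagens and matrix genes (median -0.22, adjusted p = 0.0447). Markers of dendritic and Langerhans cells rose (10 of 12 above 0, median 0.15, adjusted p = 0.00222), as did markers of ciliated epithelium (15 of 16 above 0, median 0.08, adjusted p = 0.00737). No member was called over all genes or, in the interferon list, adjusted over the list alone. The ciliated median was -0.08 without the title-series term and -0.0025 with it as a random block.

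Between the user groups, 1 gene differed in the cervix. DIO2, the deiodinase that activates thyroid hormone, was 2.47-fold higher with the LNG-IUS than with DMPA (log2 difference 1.30 ± 0.24, n = 17 and 15), and 16 of 17 LNG-IUS samples lay above the DMPA mean. PGR was at 0.72 ± 0.23 (adjusted p = 0.535), PAEP at 0.26 ± 0.26 and IGFBP1 at -0.15 ± 0.07. The adjusted p of DIO2 by limma with Benjamini-Hochberg adjustment was 0.0207, and 1103 genes had an unadjusted p under 0.05. With only PR samples no gene was called, and DIO2 had an adjusted p of 0.105 (range over its alternatives 0.0119 to 0.105).

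By camera 9 lists differed between the user groups in the cervix, and none of the 9 calls held with an estimated correlation (lowest adjusted p = 0.486 with an estimated correlation). Ribosomal protein genes were lower with the LNG-IUS (16 of 16 below 0, median -0.07, adjusted p = 5.07e-06), as were interferon-stimulated genes (18 of 19 below 0, median -0.21, adjusted p = 0.000333). Markers of natural killer cells (median 0.11), cell cycle genes (0.14), collagens and matrix (0.17), metallothioneins (0.27), estrogen-induced genes (0.08), immediate-early genes (0.10) and secretory-phase genes (0.10) were higher. Adjusted over the list alone, 3 estrogen-induced genes were called, and over all genes no member of that list was.

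**Figure D1:**
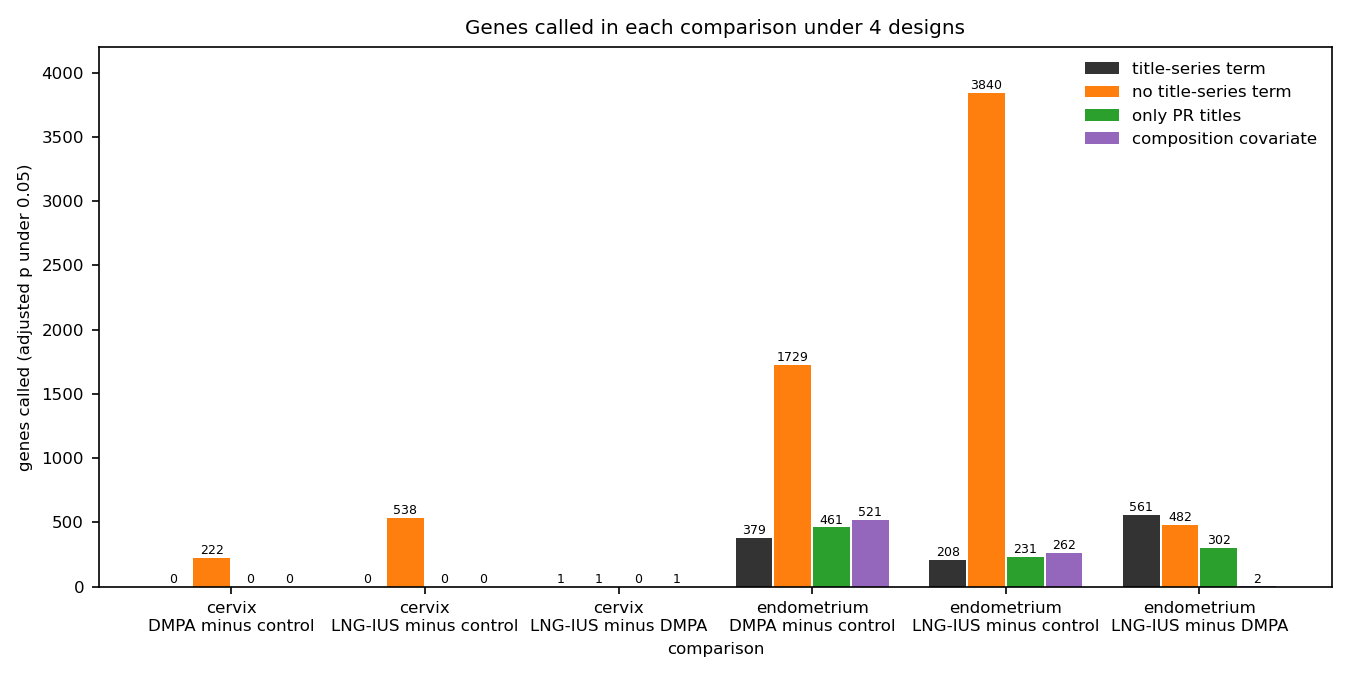
Bars give the number of genes called by limma (vertical axis, genes with adjusted p under 0.05) in each comparison under 4 designs: the title-series term, no such term, only PR samples, and a composition covariate. Calls against control in the cervix (222 and 538) appear without the title-series term, and the 561 endometrial calls between users fall to 2 with the composition covariate.

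The endometrium of DMPA users was compared with mid-secretory control endometrium. HBB (Entrez gene 3043) was 37.9-fold higher (log2 change 5.25 ± 0.86, n = 8 and 3), and HBD, the delta chain of hemoglobin, rose by 1.34 ± 0.36. Without control replicate 3, HBB was at 4.53 and lost its call (limma, adjusted p = 0.0570, range over its alternatives 1.32e-05 to 0.0570), and without the title-series term it was at 3.03. SST, the gene of the peptide hormone somatostatin, rose by 3.25 ± 0.84, the chloride channel gene CFTR by 2.53 ± 0.61, CLU, a secreted chaperone, by 1.93 ± 0.53, NEDD9 by 1.58 ± 0.39 and CHL1 by 1.57 ± 0.40. WNT7A, a Wnt ligand of the luminal epithelium, rose by 0.99 ± 0.27 and ESR1 by 0.71 ± 0.19. Genes that fell included GAST, the gastrin gene (-3.28 ± 0.82), TCN1, a vitamin B12 carrier (-3.16 ± 0.79), PHYHIPL (-3.13 ± 0.74), the monoamine transporter SLC18A2 (-2.84 ± 0.54), the glutamate transporter SLC1A1 (-2.64 ± 0.70) and AOX1, an aldehyde oxidase (-2.63 ± 0.54). HSD17B2, which inactivates estradiol and is induced by progesterone, fell by 2.19 on the log2 scale, ARG2, a mitochondrial arginase, by 1.97, and SGK1, a kinase induced by steroids, by 1.91. All 8 DMPA samples lay on the same side of the control mean for each of these genes.

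Over all genes 379 were called in this comparison, 53 higher and 326 lower, of which 12 and 55 changed more than 2-fold (limma, Benjamini-Hochberg). Adjusted p was 0.0014 for HBB, 0.00561 for SLC18A2, 0.0103 for AOX1, 0.0117 for HSD17B2 and 0.0497 for ESR1. PAEP was at -1.12 ± 0.95 (adjusted p = 0.576), CXCL8 at 1.58 ± 1.00, the decidual hormone PRL at 1.00 ± 1.04 and the proliferation marker MKI67 at -0.51 ± 0.32, and none of these passed. The count was 663, 30 and 20 without control replicates 1, 2 and 3, which kept 7, 2 and 1 of the 18 named calls. The median ratio of these 18 changes to those with all controls was 0.994, 1.03 and 0.981. Each such fit also had fewer controls, so the lost calls cannot be laid to a single control. With only PR samples 14 of the 18 held. The fold of 2, 1 and 4 of the 18 genes moved by over 1.5 times without control replicates 1, 2 and 3: without replicate 3 TCN1 was at -2.10, GAST at -4.10 and AOX1 at -1.91, without replicate 2 TCN1 was at -3.94, and without replicate 1 GAST was at -2.63 and AOX1 at -3.52. The count was 1729 without the title-series term, 861 with it as a random block, 1186 with both tissues in 1 fit, 2706 in that fit with a title-series term shared by the tissues, 2345 with array weights and 243 after renewed quantile normalization, and PAEP was at 0.35 without the term. Of the 379 genes 14.0% were higher, against 30.9% without the term, 24.9% with the block, 31.5% with the shared term, 28.7% with array weights and 23.9% after quantile normalization. Without the term 243 of the 379 genes were called again, and AOX1 (-1.05), SLC1A1 (-0.998), NEDD9 (0.80) and ESR1 (0.35) lost their calls. The fold of 9 of the 18 genes moved by over 1.5 times there, that of CFTR to 1.85, GAST to -1.95, TCN1 to -2.16, PHYHIPL to -2.39 and ARG2 to -1.31 on the log2 scale.

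By camera 17 lists shifted in the endometrium with DMPA, and none of the 17 calls held with an estimated correlation (lowest adjusted p = 0.714 with an estimated correlation). Progesterone-responsive secretory-phase genes fell (21 of 25 below 0, median log2 change -1.12, adjusted p = 1.58e-05; adjusted p = 0.714 with an estimated correlation), with 2 members called lower over all genes, HSD17B2 and ARG2, and 9 adjusted over the list alone. Erythrocyte markers rose (8 of 8 above 0, median 0.44, adjusted p = 0.000146), with 2 members called and 3 adjusted over the list alone. Markers of ciliated epithelium rose (15 of 16 above 0, median 0.43, adjusted p = 0.000216), as did genes of MHC class II antigen presentation (8 of 8, median 0.76, adjusted p = 0.00659). Estrogen-induced genes rose (12 of 17 above 0, median 0.32, adjusted p = 0.0468), with 2 called, ESR1 and WNT7A, and 3 higher and 1 lower adjusted over the list alone. Cell cycle genes fell (22 of 22 below 0, median -0.27, adjusted p = 0.0115), as did metallothioneins (median -1.13), collagens and matrix (-0.61) and endothelial markers (-0.26, with 4 members lower adjusted over the list alone). Without control replicates 1, 2 and 3, 8, 7 and 14 of the 17 list calls held. Those of the secretory-phase, ciliated and erythrocyte lists held each time, and that of the estrogen-induced list was lost each time. The metallothionein median was -0.63 without replicate 1, and the endothelial median was -0.03 without replicate 2.

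The other lists that rose with DMPA held markers of neutrophils (13 of 13 above 0, median 0.49), B and plasma cells (12 of 12, 0.20), dendritic cells (0.29) and T cells (0.17), T cell and interferon-induced chemokines (0.37), mucins (0.34), antimicrobial peptides (0.23) and squamous differentiation genes (0.15). None of these calls held with an estimated correlation (adjusted p 0.714 to 0.813 with an estimated correlation). The squamous median was -0.01 after renewed quantile normalization and -0.20 in 1 fit of both tissues with a shared title-series term.

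**Figure D2:**
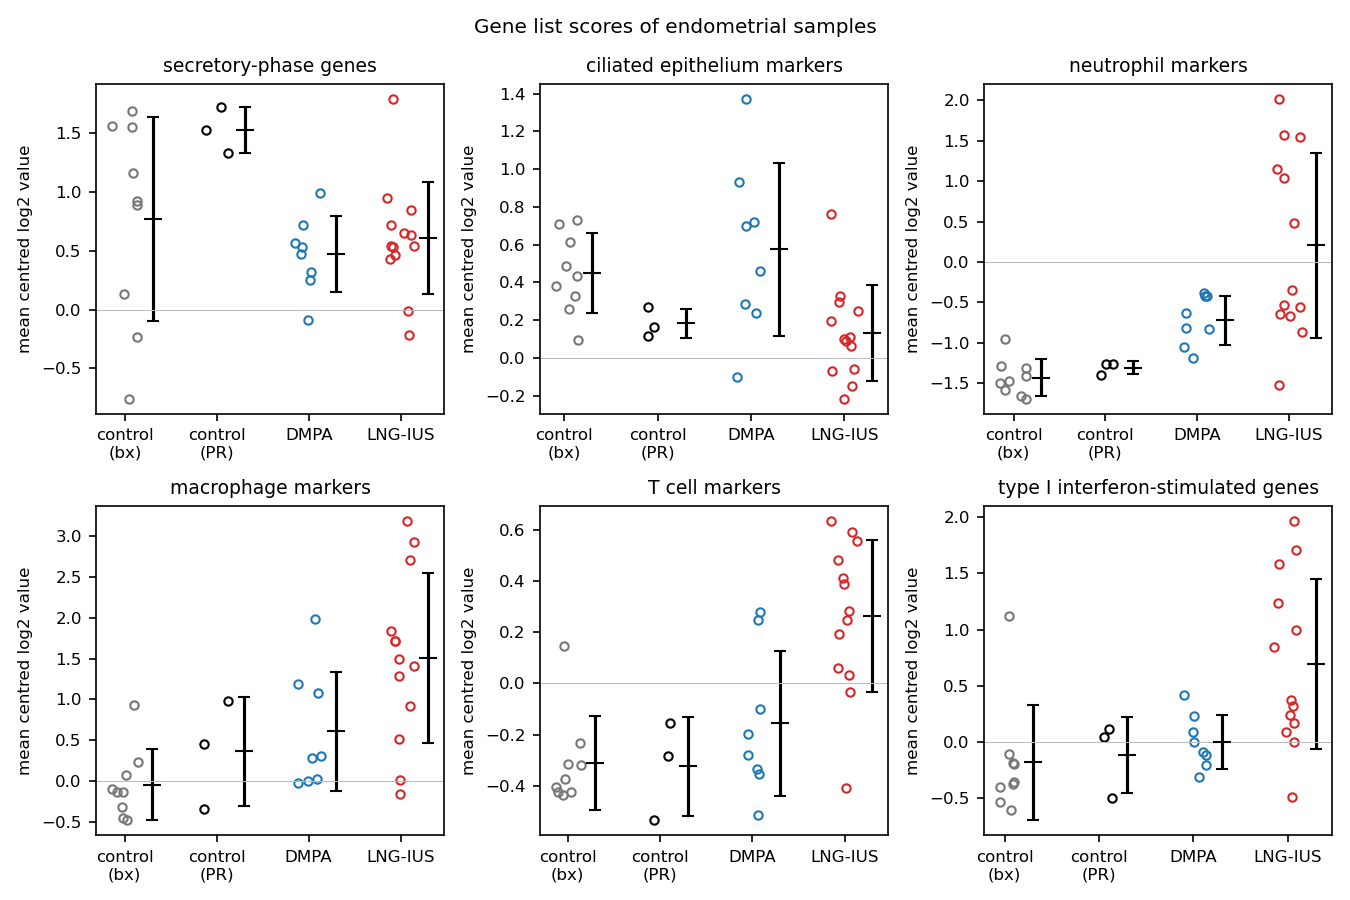
Each point is 1 endometrial sample and gives the mean centred log2 value of the measured genes of a list (vertical axis) by group (horizontal axis), and bars show the mean ± SD. The secretory-phase score averaged 1.53 in PR controls, 0.47 with DMPA and 0.61 with the LNG-IUS, and the neutrophil marker score averaged -1.31, -0.72 and 0.20.

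The endometrium of LNG-IUS users was compared with the same controls. HBB rose by 4.67 ± 0.81 on the log2 scale (25.5-fold, n = 13 and 3, 13 of 13 samples above the control mean). Without control replicate 3 it was at 3.95 and lost its call (limma, adjusted p = 0.106, range over its alternatives 3.87e-06 to 0.106), and without the title-series term it was at 2.46. Genes that also rose included CCL2, a monocyte chemokine, by 2.96 ± 0.67, IL1RN, the interleukin 1 receptor antagonist, by 2.91 ± 0.67, TREM1, an activating receptor of myeloid cells, by 2.98 ± 0.75, IL7R, a receptor of T cells, by 2.90 ± 0.59, the chemokine CXCL16 by 1.96 ± 0.47 and the T cell antigen CD5 by 0.87 ± 0.21. The matrix metalloproteinases MMP7 (3.75 ± 0.95) and MMP9 (2.68 ± 0.70) and the cannabinoid receptor CNR1 (2.49 ± 0.64) also rose. Among the genes named as lower with DMPA, those that also fell were PHYHIPL (-3.29 ± 0.70), GAST (-3.17 ± 0.78), SLC1A1 (-2.58 ± 0.66), SLC18A2 (-2.19 ± 0.51), HSD17B2 (-1.96 ± 0.43) and ARG2 (-1.91 ± 0.43). The glycosyltransferases GCNT3 (-2.49 ± 0.47) and B4GALNT3 (-2.37 ± 0.42) fell as well.

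Over all genes 208 were called with the LNG-IUS, 30 higher and 178 lower, of which 16 and 54 changed more than 2-fold (limma, Benjamini-Hochberg). Adjusted p was 0.00286 for HBB, 0.00466 for B4GALNT3, 0.00839 for GCNT3, 0.0144 for IL7R and 0.0486 for MMP9. CXCL8 was at 3.46 ± 0.95 (adjusted p = 0.0597), the decidual genes PRL at 2.78 ± 0.98 (adjusted p = 0.147) and IGFBP1 at 2.05 ± 1.13 (0.93 and 3.27 without control replicates 1 and 3), the macrophage marker CD163 at 1.94 ± 0.67, the T cell gene CD3D at 0.76 ± 0.25 and PAEP at -0.81 ± 0.90, and none passed with the title-series term. The count was 283, 21 and 5 without control replicates 1, 2 and 3, which kept 4, 2 and 0 of the 18 named calls, and GAST was at -2.51 without replicate 1 and -3.98 without replicate 3. With the controls complete, 12 of the 18 held with only PR samples and 12 with a covariate for tissue composition. Under that covariate PRL was at 2.00 and IGFBP1 at 1.35, while CXCL8 was at 3.36. The count was 3840 without the title-series term, 2048 with it as a random block, 1173 with both tissues in 1 fit, 2920 in that fit with a title-series term shared by the tissues, 2087 with array weights and 123 after renewed quantile normalization, and PAEP was at 0.65 without the term, 0.34 with the block and 0.11 with the shared term. Of the 208 genes 14.4% were higher, against 41.9% without the term, 45.2% with the block, 39.0% with both tissues in 1 fit, 42.1% with the shared term and 28.7% with array weights. Without the term 167 of the 208 genes were called again, and SLC1A1 (-0.94) lost its call. PHYHIPL (-2.55), GAST (-1.84), B4GALNT3 (-1.54) and ARG2 (-1.25) moved by over 1.5 times there, and CXCL8 (3.51), PRL (3.35), IGFBP1 (3.62), CD163 (2.36) and CD3D (0.64) were called.

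By camera 23 lists shifted in the endometrium with the LNG-IUS, and none of the calls held with an estimated correlation (lowest adjusted p = 0.0970 with an estimated correlation). Without control replicates 1, 2 and 3, 21, 20 and 23 of the 23 calls held. T cell markers rose (13 of 13 above 0, median 0.59, adjusted p = 1.18e-11; adjusted p = 0.145 with an estimated correlation), with 1 member called and 9 adjusted over the list alone. Neutrophil markers rose (13 of 13, median 1.35, adjusted p = 2.07e-11; adjusted p = 0.187 with an estimated correlation), with 0 called by limma and 12 adjusted over the list alone. Inflammatory chemokines and cytokines rose (18 of 19, median 1.36), with 1 called higher and, adjusted over the list alone, 11 higher and 1 lower. Macrophage markers rose (14 of 14, median 1.07; 4 adjusted over the list alone), as did interferon-stimulated genes (18 of 19, median 0.77), T cell and interferon-induced chemokines (12 of 13, median 1.22), dendritic cell markers (12 of 12, median 0.40) and MHC class II genes (7 of 8, median 0.90).

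The hormone and tissue lists also moved with the LNG-IUS by camera, and these calls too were lost with an estimated correlation (adjusted p 0.187 to 0.606 with an estimated correlation). Secretory-phase genes fell (21 of 25 below 0, median -0.93, adjusted p = 1.95e-05; adjusted p = 0.236 with an estimated correlation), with 2 called and 7 adjusted over the list alone. Metallothioneins fell (8 of 9 below 0, median -1.43; 5 adjusted over the list alone), as did columnar epithelial markers (11 of 15 below 0, median -0.78; 3 adjusted over the list alone), endothelial markers (-0.21) and ribosomal protein genes (-0.11). Metalloproteinases and inhibitors rose (16 of 18 above 0, median 0.73, 2 called), as did genes of decidualized stroma (13 of 17, median 0.28, 1 called), erythrocyte markers (8 of 8, median 0.38, 1 called), pattern recognition genes (0.63), immediate-early genes (0.41), genes of HIV entry (0.30), hypoxia genes (0.26), B and plasma cell markers (0.24), antimicrobial peptides (0.15) and squamous genes (0.06). The squamous median was -0.06 after renewed quantile normalization and -0.36 in 1 fit of both tissues with a shared title-series term (adjusted p = 0.611). In that fit camera put the endothelial markers higher, while their median stayed below 0, at -0.09 (adjusted p = 0.650).

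**Figure D3:**
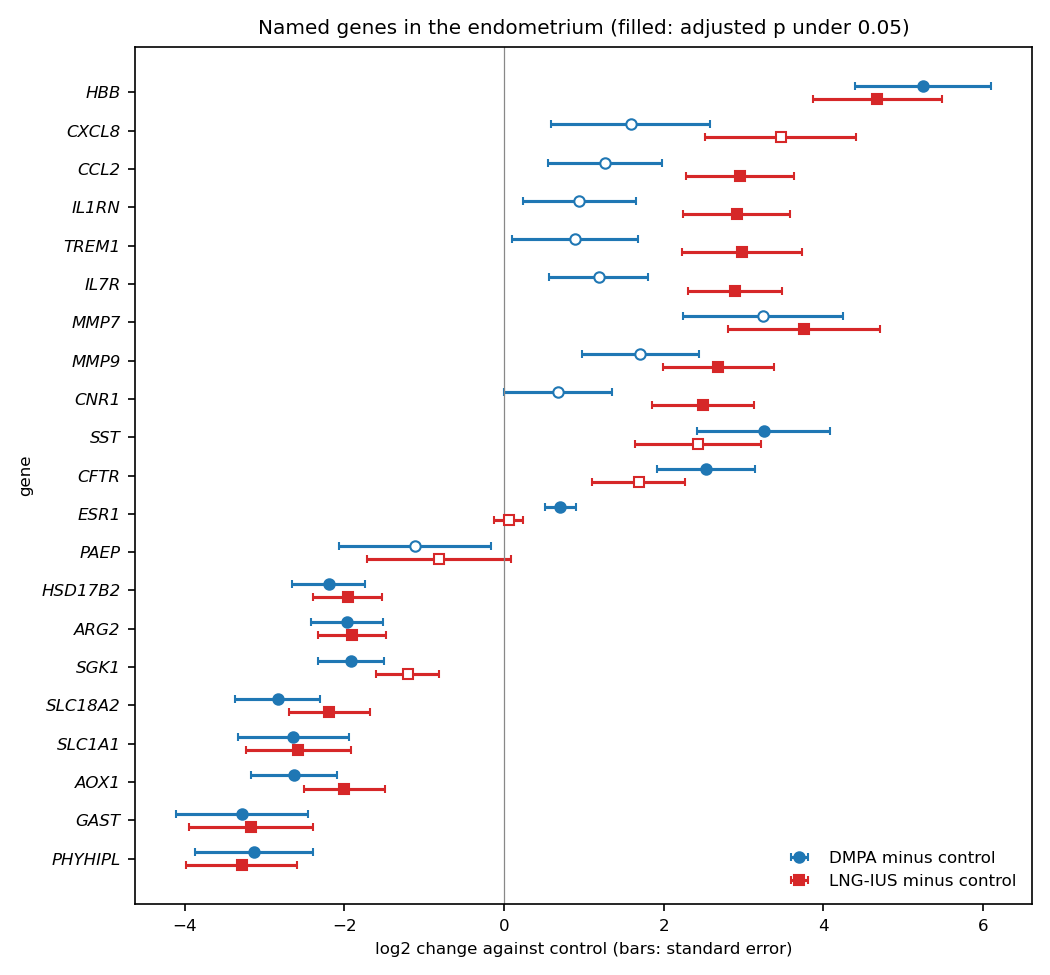
Points give the log2 change of named genes (vertical axis) in the endometrium of DMPA and LNG-IUS users against control (horizontal axis), bars the standard error, and filled points an adjusted p under 0.05. HBB was highest in both groups (5.25 and 4.67), and GAST and PHYHIPL were below -3 in both.

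The changes of both user groups were compared with each other. In the endometrium 5 genes were called higher and 109 lower in both groups, and none in opposite directions. Without control replicates 1, 2 and 3, 7, 1 and 0 were higher and 214, 11 and 4 lower in both. Independent lists of these sizes would share 0.0866 and 3.16 genes, and unchanged groups simulated against the same controls shared 0.09 and 0.17 on average. Independent lists ignore the shared controls, and the simulated groups had no change. Neither figure therefore shows what overlap the shared controls give to lists of these sizes. Across genes, which are not independent replicates, the changes correlated at r = 0.709, and simulated unchanged groups gave 0.771 (0.393 to 0.933) because the controls are shared. The covariance was 0.0792 against 0.0330 simulated (0.00916 to 0.0691), a difference of 0.0462. With 3 PR controls no split kept 2 in each part, so part of the excess may come from the shared controls. In the cervix r was 0.513 against 0.639 simulated, and the covariance was 0.00612 against 0.0121. When the 7 controls were split into 3 and 4, the mean r over 70 splits was -0.281 and the covariance -0.0079.

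The user groups were also compared directly in the endometrium. The controls do not enter these log2 differences, but they do enter the estimate of the spread. The groups differed in dose, route and drug together. LGR5, a Wnt pathway receptor of epithelial progenitors, was 6.91-fold lower with the LNG-IUS than with DMPA (log2 difference -2.79 ± 0.52, n = 13 and 8, 13 of 13 samples). Other genes lower with it were VTCN1, an immune checkpoint ligand (-1.81 ± 0.49), FGF9 (-1.51 ± 0.36), PAX2 (-1.32 ± 0.36), PATJ, a tight junction scaffold (-1.15 ± 0.27), FGFR2 (-1.14 ± 0.24) and ESR1 (-0.65 ± 0.13). Higher were CHRDL1, an antagonist of bone morphogenetic proteins (2.29 ± 0.52), the antisense RNA PAPPA-AS1 (2.09 ± 0.41), TREM1 (2.09 ± 0.53), IL1RL1, the interleukin 33 receptor (2.08 ± 0.56), IL1RN (1.97 ± 0.47), AQP9, a neutrophil aquaglyceroporin (1.91 ± 0.51), CNR1 (1.82 ± 0.45) and HSD11B1, which forms cortisol from cortisone (1.83 ± 0.49). Also higher were FN1 (1.46 ± 0.30), TIMP1 (1.30 ± 0.30), THY1 (1.58 ± 0.44), DUSP1 (1.41 ± 0.28) and ZFP36 (1.20 ± 0.23).

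Over all genes 561 differed between the user groups, 253 higher and 308 lower with the LNG-IUS, of which 41 and 9 differed more than 2-fold (limma, Benjamini-Hochberg). Adjusted p was 0.0222 for LGR5, ESR1, PAPPA-AS1, DUSP1 and ZFP36 and 0.0257 for CHRDL1. CXCL8 was at 1.88 ± 0.66 (adjusted p = 0.0912), CD163 at 1.48 ± 0.47, CD3D at 0.54 ± 0.17, PRL at 1.77 ± 0.69 and PGR at -0.40 ± 0.22, and none passed. With a covariate for the balance of columnar and stromal markers 2 genes were called and 0 of the 33 named calls held (limma, adjusted p 0.0759 to 0.296), although the median of their changes was 0.853 of the value before: IL1RN went from 1.97 ± 0.47 to 2.04, but LGR5 from -2.79 ± 0.52 to -1.90, VTCN1 from -1.81 ± 0.49 to -0.91, PAX2 from -1.32 ± 0.36 to -0.72 and THY1 from 1.58 ± 0.44 to 0.78. THY1 belongs to the stromal list that forms this covariate, so part of its own shift is built in. PRL, not called before, went from 1.77 ± 0.69 to 0.85 under the covariate, while CXCL8 went from 1.88 ± 0.66 to 1.75. Of the 33 calls 32 held without the title-series term, and PAX2 was lost. With only PR samples 302 genes were called and 14 of the 33 named calls held (limma, adjusted p 0.0256 to 0.0842), with TREM1, IL1RN, VTCN1 and CHRDL1 among the 19 lost. With array weights 929 genes were called, with both tissues in 1 fit 2178 and in that fit with a shared title-series term 2128, and median centring gave 263 higher and 174 lower, 60.2% higher against 45.1%.

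By camera 27 lists differed between the user groups in the endometrium, and none of the 27 calls held with an estimated correlation (lowest adjusted p = 0.327 with an estimated correlation). Immune lists were higher with the LNG-IUS: T cell markers (13 of 13 above 0, median 0.47, adjusted p = 7.59e-08), with 4 called, CD3G and TRAT1 among them, and 9 adjusted over the list alone; interferon-stimulated genes (19 of 19, median 0.82, adjusted p = 7.59e-08), with MX2 called (1.27 ± 0.34) and 12 adjusted over the list alone; and pattern recognition genes (17 of 19, median 0.58), with 4 called, MRC1 (1.66 ± 0.43) and TLR2 (1.46 ± 0.37) among them, and 11 adjusted over the list alone. Inflammatory chemokines and cytokines were higher (18 of 19, median 0.85), with CCL2 called (1.69 ± 0.47), as were macrophage markers (14 of 14, median 0.78) and neutrophil markers (13 of 13, median 0.77), with 1 called in each. Markers of ciliated epithelium were lower (16 of 16 below 0, median -0.38, adjusted p = 6.68e-08), with RSPH1 (-0.85 ± 0.24) and DNAI2 (-0.37 ± 0.08) called and 15 adjusted over the list alone. Columnar markers (15 of 15 below 0, median -0.44) and estrogen-induced genes (median -0.27, with 2 called and 4 adjusted over the list alone) were lower too.

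Immediate-early and handling response genes were higher with the LNG-IUS in 15 of 15 members (median 0.47, adjusted p = 6.68e-08; adjusted p = 0.327 with an estimated correlation), with 3 called and 8 adjusted over the list alone. Higher as well by camera, with every call lost with an estimated correlation (adjusted p 0.327 to 0.696 with an estimated correlation), were lists of stroma (median 0.46), collagens and matrix (0.44), metalloproteinases (0.47), smooth muscle (0.29), angiogenesis (0.35), hypoxia (0.26), glucocorticoid response (0.28), complement (0.40), HIV entry (0.34), T cell and interferon-induced chemokines (0.71), cell cycle (0.09), and markers of natural killer cells (0.31), dendritic cells (0.16) and B and plasma cells (0.06). Mucins and trefoil factors (-0.22), cell junctions (-0.14) and ribosomal proteins (-0.09) were lower, and these calls were lost likewise (adjusted p 0.453 to 0.579 with an estimated correlation). The composition score, columnar minus stromal markers, was at -0.75 ± 0.40 with the LNG-IUS against DMPA (exact permutation test, 2-sided, p = 0.0565), and 18 of the 25 lists tested under that covariate kept their call at the preset correlation, as did 19 of 27 after renewed quantile normalization.

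Whether the contraceptives changed the tissues differently was tested by the interaction. With DMPA, HBB rose more in the endometrium than in the cervix, by 4.67 ± 1.01 (3.95 without control replicate 3, where the call was lost), and GAST (-3.40 ± 0.63), PHYHIPL (-3.21 ± 0.57), AOX1 (-2.62 ± 0.44) and SGK1 (-2.03 ± 0.43) changed more toward lower values. Without control replicates 1 and 3 GAST was at -2.74 and -4.21 and AOX1 at -3.50 and -1.89. With the LNG-IUS, HBB (4.95 ± 0.97), CCL2 (3.22 ± 0.64) and CXCL8 (3.75 ± 0.98) moved higher in the endometrium than in the cervix, with HBB at 4.23 without control replicate 3, and CXCL8 lost its call without control replicate 2 (3.71) and without control replicate 3 (3.78). The difference between the user groups depended on tissue for LGR5 (-2.88 ± 0.46) and for DIO2 (-1.95 ± 0.42). The interaction called 293 genes for DMPA (31 higher, 262 lower), 347 for the LNG-IUS (122 higher, 225 lower) and 207 for the LNG-IUS against DMPA (135 higher, 72 lower) by limma with Benjamini-Hochberg adjustment. With each tissue's own spread the counts were 110, 87 and 6, and CXCL8 and DIO2 lost their calls (adjusted p = 0.0909 and 0.0699; ranges over their alternatives 3.33e-05 to 0.0909 and 0.00677 to 0.0699). Without control replicates 1, 2 and 3 the first count was 647, 102 and 111 and the second 453, 162 and 102, with 8, 7 and 6 of the 9 named calls kept in the first and 7, 8 and 6 of 10 in the second. These counts were 1836 and 3242 without the title-series term, 28.3% and 45.1% higher against 10.6% and 35.2%, with HBB at 2.67 and 2.95, and for DMPA GAST at -1.94, PHYHIPL at -2.39 and AOX1 at -1.07.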

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

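The tests of explanations, the counts over other splits of the samples and the fits with each tissue's own spread or without a control in this part were chosen only after the results had been seen.

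Among the 8 endometrial DMPA samples, the highest or lowest sample stood far from the others for 2 of 37 list scores and 9 of 59 genes, where chance gives about 1 in 20. The squamous score was -2.57 in replicate 1 (others -3.34 to -3.11), and the B and plasma cell score was -0.56 in replicate 5 (others -0.35 to -0.20). In replicate 1, SST was at 0.46 (others 2.65 to 4.51) and PAEP at 1.82 (others 3.97 to 5.17). In replicate 4, IL1RL1 was at 4.02, CNR1 at 3.07 and HSD11B1 at 1.65, above highest other values of 1.42, 0.87 and 0.56. In replicate 8, GAST was at 1.23, PHYHIPL at 2.69 and AOX1 at 0.20, above highest other values of 0.24, 1.31 and -0.27. TRAT1 was at 0.25 in replicate 2, above -0.22.

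The change between endometrium and cervix was called by limma for 293 genes with DMPA, 347 with the LNG-IUS and 207 for the LNG-IUS against DMPA. With DMPA the named differences were HBB (4.67), SST (3.39), LGR5 (2.38), GAST (-3.40), PHYHIPL (-3.21), PLA2G2A (-3.11), AOX1 (-2.62), HSD17B2 (-2.04) and SGK1 (-2.03) on the log2 scale. With the LNG-IUS they were HBB (4.95), CXCL8 (3.75), CCL2 (3.22), the neutrophil gene S100A8 (3.17), PRL (2.76), CRISP3 (-4.16), PHYHIPL (-3.32), GAST (-3.27), HSD17B2 (-2.10) and CLDN4 (-1.88). For the LNG-IUS against DMPA they were CHRDL1 (2.52), CCL2 (2.10), HSD11B1 (1.85), MRC1 (1.63), MX2 (1.44), ESR1 (-0.63), DIO2 (-1.95) and LGR5 (-2.88). Without endometrial control replicate 1, values for DMPA were 3.07 (LGR5), -2.74 (GAST) and -3.50 (AOX1), and GAST was at -2.61 with the LNG-IUS; HSD17B2 (-1.73 with DMPA and -1.80 with the LNG-IUS), CRISP3 (-3.88) and PRL (2.30) lost their calls. Without replicate 2, PLA2G2A (-2.11) and LGR5 (1.83) with DMPA and CXCL8 (3.71) and PRL (2.65) with the LNG-IUS lost their calls, and CRISP3 was at -4.76. Without replicate 3, values for DMPA were 3.95 (HBB, which lost its call), -4.21 (GAST), -4.36 (PLA2G2A) and -1.89 (AOX1), and for the LNG-IUS 4.23 (HBB) and -4.08 (GAST). Calls were lost there too for LGR5 (2.23) and HSD17B2 (-1.98) with DMPA and CXCL8 (3.78), S100A8 (2.96), CRISP3 (-3.84) and HSD17B2 (-2.04) with the LNG-IUS. PLA2G2A (-1.52) lost its call without the title-series term. With only PR samples 9 of 9, 8 of 10 and 7 of 8 of these kept their call. With each tissue's own spread 5 of 9, 5 of 10 and 1 of 8 did, the last being LGR5.

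Rows outside the gene-level comparisons also passed the test. Of the 7807 rows not listed in the annotation, 57 were called in the endometrium with DMPA, 46 higher and 11 lower. The 379 genes called there were mostly lower (53 higher, 326 lower). For the LNG-IUS against DMPA 34 such rows were called, 5 higher and 29 lower. The cause of these directions was not tested. Of the 1752 rows with several symbols, 29 were called in the endometrium with DMPA, 7 with the LNG-IUS and 1 in the cervix with DMPA.

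Counts of called genes were set against 100 splits of the samples into groups of the same sizes, the real one included. As many genes as the real split came from 4 splits for endometrial DMPA (379 genes, highest other 1231), 1 for endometrial LNG-IUS (208, highest other 97) and 1 for the LNG-IUS against DMPA (561, highest other 313). Few splits also matched the interactions, with 4 for DMPA (293, highest other 641), 3 for the LNG-IUS (347, highest other 827) and 2 between users (207, highest other 707). The same held for the control tissues with 1 (3870, highest other 1385) and for the cervix between users with 3 (1, highest other 1031). Each of these shares was under 5%, but they were not adjusted over the comparisons, and the cervical one rested on 1 gene. They therefore do not exclude chance. For cervical DMPA and LNG-IUS all 100 splits gave at least the real 0 genes (highest others 46 and 18). A real count of 0 fixes that outcome in advance, so it carries no information. Splits with 1231 calls against 379 and 1031 against 1 may reflect some structure of the samples other than the groups. Neither such structure nor its form (a few arrays, unequal spread or a hidden grouping) was tested.

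Genes were called in the cervix against control, 222 with DMPA and 538 with the LNG-IUS, when both title series of controls were pooled, and none were when the comparison was made within the PR series. A difference between the title series is a candidate explanation: the 2 kinds of cervical control differed in 856 genes, and 2 of 100 splits of these 20 controls into 13 and 7 gave as many, the highest other 1407. In the endometrium, the 9 bx and 3 PR controls differed in 13 genes, and 2313 had an unadjusted p under 0.05 by limma. With 3 PR controls, that count does not show how alike the 2 kinds were there. In the cervix, the smaller number of controls may also play a part. Of 100 random sets of 7 controls, 17 gave no call with DMPA and 26 none with the LNG-IUS. All these sets had 7 controls, and whether genes were called went with their share of bx controls. The 57 sets with 5 or more bx controls gave calls in 57 and 56 cases, and the 43 with 4 or fewer in 26 and 18. The number alone thus did not set whether genes were called. It was not varied in these sets, so a part played by it is not excluded. The 222 and 538 genes had median absolute changes of 0.30 and 0.25 with all controls and of 0.15 and 0.09 within the PR series. Within that series 221 and 523 of them kept their sign, and 85 and 65 had an unadjusted p under 0.05 by limma. The PR controls are part of the pooled set, so some of this agreement is built in. A small effect of the contraceptives stays open, untested.

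HBB was higher in the endometrium of both user groups than in the 3 PR controls. Blood in the users' biopsies may account for it: the mean of the other 7 erythrocyte genes was higher with DMPA by 0.50 ± 0.10 (exact permutation test, 2-sided, p = 0.0121), but the 0.43 ± 0.13 with the LNG-IUS did not pass (exact p = 0.0929). Users also exceeded the 9 bx controls, by 2.30 ± 0.49 with DMPA and 1.72 ± 0.64 with the LNG-IUS (exact permutation test, 2-sided, p = 0.000535 and 0.0160). This does not decide on low HBB in the PR controls alone, because title series and use cannot be told apart there. Without the title-series term the change went from 5.25 to 3.03 with DMPA and from 4.67 to 2.46 with the LNG-IUS. The size of the rise thus depended on the controls used. Uterine bleeding under progestins, a biological source of blood, stays open and was not tested.

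Leukocyte markers were higher in the endometrium with the LNG-IUS than with DMPA, by 0.75 ± 0.25 for the mean of neutrophil, macrophage and T cell markers (exact permutation test, 2-sided, p = 0.0201). Erythrocyte markers were not higher with the LNG-IUS, at -0.14 ± 0.17 (exact p = 0.512). Leukocyte minus erythrocyte markers were higher by 0.89 ± 0.21 (exact p = 0.00167). The leukocyte lists were chosen after they were seen to be higher, which favours that result. It speaks against more blood as the whole cause only if blood raises both kinds of marker alike, which was not tested. A lower share of epithelium stays open: leukocyte minus vessel markers differed by 0.53 ± 0.27 (exact p = 0.122), which does not decide. Handling of the tissue stays open too, since immediate-early and handling response genes were also higher with the LNG-IUS (15 of 15 members, median 0.47, camera adjusted p = 6.68e-08; adjusted p = 0.327 with an estimated correlation), and their part in the difference was not tested. The device in the uterus, the drug and its dose stay open and cannot be told apart in this design.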

How the results depend on the processing

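Alternatives with the lowest-SD genes left out, a trend in eBayes, each tissue's own spread, both tissues in 1 fit with a title-series term in each, and PR controls left out between tissues were chosen after seeing the data; the others were planned. Leaving out the genes of lowest mean was not run, because a table centred per gene has no mean level, and the signal over background that limits dim genes is not known. Named genes kept direction and side of the threshold in 1673 of 1963 applications of a setting, lost the call in 247, gained one in 34 and reversed in 9. Lists did so in 1293 of 1509, lost the call in 207 and reversed in 9. Camera with an estimated correlation, which lost every list call, is not part of this tally. Part of the gene tally was fixed in advance, because named genes that were not called and stayed so count as kept. Only PR samples, robust eBayes, a trend, the lowest-SD genes left out and each tissue's own spread cannot move a log2 change. Both tissues in 1 fit with a term in each cannot either. Leaving out the title-series term or a control cannot move those between users. The tally therefore does not measure how stable the calls were. Comparisons with endometrial control rested on 3 samples. Leaving out a PR control or the bx controls also lowers the number of samples in the fit. Beyond that and the fits of both tissues below, the cause was not tested for any change given here.

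Without the title-series term, calls went from 0 to 222 (cervix DMPA), 0 to 538 (cervix LNG-IUS), 379 to 1729 (endometrium DMPA) and 208 to 3840 (endometrium LNG-IUS), and interactions from 293 to 1836 and 347 to 3242. As a random block it gave 861 and 2048 in the endometrium. Both tissues in 1 fit, with a title-series term in each, gave 2 in the cervix between users and 1186, 1173 and 2178 in the endometrium (DMPA, LNG-IUS, between users), at the same log2 changes and another estimate of the spread. That fit with a shared term gave 2, 2706, 2920 and 2128, and interactions, always fitted over both tissues, of 2139 and 3404. With only PR samples 0 (cervix between users), 302 (endometrium between users) and 112 (its interaction) were called. Quantile normalization gave 2, 243 and 123, and array weights 2, 2345, 2087 and 929, for cervix between users, endometrium DMPA, LNG-IUS and, for weights, between users. The composition covariate left 2 of 561. Each tissue's own spread gave interactions of 110, 87 and 6. Leaving out 1 PR endometrial control gave 20 to 663 for DMPA, 5 to 283 for the LNG-IUS, 465 to 569 between users, interactions of 102 to 647 and 102 to 453, and 2419 to 3662 between control tissues. With an estimated correlation 0 lists were called where 8, 4, 9, 17, 23, 27, 11, 20 and 19 had been. The correlation of both endometrial changes was 0.904 over the 473 genes called in either, a set chosen by change against the same controls. As many genes of lowest p in simulated unchanged groups gave 0.926 (0.739 to 0.983), so 0.904 does not show a shared change.

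Participant as a replicate block, the pairing of the tissues, gave 324, 367 and 226 interaction calls and 3907 between control tissues, and changed no named call.

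Signs reversed for PGR, cervix LNG-IUS minus control, without the title-series term (-0.31), with it as a random block (-0.17), after quantile normalization (-0.032) and with array weights (-0.039). PAEP, endometrium DMPA minus control, was at 0.35 without the term and 0.039 as a block, and PAEP, endometrium LNG-IUS minus control, at 0.65, 0.34 and, in 1 fit with a shared term, 0.11. The cell cycle list (cervix DMPA) was at 0.19 and 0.034 without the term and as a block, and ciliated markers (cervix LNG-IUS) at -0.077 and -0.0025. Squamous genes in the endometrium were at -0.015 (DMPA) and -0.063 (LNG-IUS) after quantile normalization and at -0.20 and -0.36 in 1 fit with a shared term. In that fit camera's direction, but not the sign of the median (-0.091), reversed for endothelial markers (LNG-IUS).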

Other observations

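The list tests below were planned, and only leaving out endometrial controls was chosen after the results had been seen. Several gene groups changed differently in the endometrium and the cervix by camera. With the LNG-IUS, interferon-stimulated genes rose more in the endometrium (19 of 19 members above 0, median log2 difference 0.96, adjusted p = 1.90e-12; adjusted p = 0.128 with an estimated correlation), with 1 member called over all genes and 12 adjusted over the list alone. Neutrophil markers did so too (13 of 13, median 1.30, adjusted p = 1.87e-12; adjusted p = 0.0946 with an estimated correlation), with 3 called and 10 adjusted over the list alone. Genes of decidualized stroma rose more (13 of 17 above 0, median 0.28), with 2 called and 3 adjusted over the list alone (adjusted p = 0.160 with an estimated correlation). For the LNG-IUS against DMPA, estrogen-induced genes were lower in the endometrium relative to the cervix (13 of 17 below 0, median -0.63; adjusted p = 0.0981 with an estimated correlation), with 2 called and 6 adjusted over the list alone, as were ciliated markers (16 of 16 below 0, median -0.43; adjusted p = 0.137 with an estimated correlation), with 1 called and 12 adjusted over the list alone. In all, 11, 20 and 19 lists were called for DMPA, the LNG-IUS and the LNG-IUS against DMPA, and none with an estimated correlation (lowest adjusted p 0.640, 0.0888 and 0.0981 with an estimated correlation). Without endometrial control replicates 1, 2 and 3, 5, 11 and 11 of the 11 calls for DMPA held, and 19, 19 and 20 of the 20 for the LNG-IUS.

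The list of steroid receptors and steroid metabolism and that of mast cell markers were called by camera in none of the 6 comparisons within a tissue, although single members were called by limma. These were ESR1 and HSD17B2 in the endometrium with DMPA, HSD17B2 with the LNG-IUS, and ESR1, HSD11B1 and the mast cell gene CPA3 (0.77 ± 0.20) for the LNG-IUS against DMPA. In the endometrium the medians of the lists were 0.05 and 0.13 with DMPA, 0.00 and 0.15 with the LNG-IUS, and 0.01 and 0.15 for the LNG-IUS against DMPA, and the lowest adjusted p was 0.0517, for mast cells with the LNG-IUS.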
